A study of Mus musculus with 5 samples.

How the data were processed

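NKX3-1, a homeodomain transcription factor of the prostate epithelium and a prostate tumour suppressor, was assayed by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole prostates of mice. The mice were 12 to 16 weeks old, per the labels. The 5 libraries came from mice with 2 intact copies of Nkx3-1 (WT, 2 libraries), with 1 intact copy (HET, 2 libraries) and with none (KO, 1 library). All were made with an antibody against the factor. Reads were placed on mouse genome build 37 and peaks were called with MACS, using the KO library as the control for nonspecific antibody binding, per the labels' protocols. The aligner, the MACS version, the peak threshold and any filter are not given in the sources used here.

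The deposited files are 1 peak list per library, headed as MACS peaks per the file headers, with the position, the number and a score of each peak. The score is the authors' own value for a peak. Its scale is not given in the sources used here, and no list holds a score below 100. Scores were used to rank peaks within a list, as percentiles in which the highest score is 100. Only the alternative with a stricter score limit applied 1 limit to all lists, which assumes that they share a scale. The lists hold no read counts, so the depth of each library is unknown and no interval that needs it is given. Peaks were called per library, not on pooled libraries, and the 4 lists of WT and HET share the single KO control. Overlap between any of these lists therefore includes whatever the shared control contributes, which peak lists alone cannot separate.

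File starts were read as 0-based and are given here 1-based. The build was checked against the positions. The gene table at hand is of GRCm38, and 9 of 21 chromosomes have a peak beyond the last gene of that build. No coordinate was converted, so genes, exons, introns and untranslated regions near peaks are not reported here, and regions are identified by position. For the same reason 3 planned results were not run, namely the location of peaks relative to genes, the test of 11 gene lists fixed beforehand, and the search for sequence motifs. Nkx3-1 itself was not analysed here as a locus.

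Peaks of the 4 WT and HET lists that shared at least 1 bp were merged into union regions, and each region was recorded as called or not called in each list. Regions in both WT lists and neither HET list are named WT-only, and the reverse HET-only. Overlap between pairs of lists was measured as the share of peaks overlapped by at least 1 bp and as the Jaccard index (shared base pairs over base pairs covered by either). Chance overlap came from 1000 random circular shifts of 1 list along each chromosome, over the span that any list covers, giving a permutation p of at least 0.001. Group differences were tested with a two-sided exact permutation of the genotype labels, which with 2 against 2 lists cannot give a p below 0.333. Shares carry a 95% Wilson interval, which covers counting error only. Peak density was counted per chromosome and in windows of 1 Mb by peak centre. Computations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.

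The regions named in the text follow a rule fixed before the data were examined: the 10 highest in mean within-list percentile among regions of all 4 lists, among WT-only and among HET-only regions, and the 3 windows with most peaks. Windows were ranked by peaks summed over the 4 lists, although ranking within each list had been planned. The rule's parts on genes could not be applied. The merging and overlap steps were run on simulated lists with known patterns. In these, 200 of 200 simulated WT-only and 2000 of 2000 simulated HET-only regions were recovered. Different simulated regions were placed so that they never touched, and no call was dropped. Full recovery therefore checks the code only, not crowded regions or calls lost near the limit. A random list overlapped the HET 1 list 1.01 times as often as chance. The alternatives were another overlap rule, a stricter score limit, lists of equal length, autosomes only, joined peaks, another null, the replicate number as a block, and each list left out in turn.

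The track lines give each list a different identifier, but no label says whether libraries of a genotype came from separate mice or pools. The p-values of genotype therefore concern only these libraries. Those from random shifts, random placements or labels permuted among regions concern positions within the lists, not spread between libraries. Replicate numbers are shared between WT and HET in the titles, and no label says that a number marks a shared batch or litter.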

Results

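The series comprised 5 ChIP-seq libraries for NKX3-1 from whole mouse prostate, of which 2 were WT, 2 HET and 1 KO for Nkx3-1. The design asked where NKX3-1 is bound and how the bound sites compare between gene doses. The deposited lists held 14608 peaks for WT 1, 11045 for WT 2, 17720 for HET 1 and 17769 for HET 2. Median peak width was 581 bp in WT 1, 613 bp in WT 2, 653 bp in HET 1 and 634 bp in HET 2. The KO library served as the control of the peak caller. The list filed under it held 2 rows, both on chromosome Y, and both equal to rows of the WT 1 list in position, peak number and score. It was therefore not treated as a KO peak list, and no value for KO is compared below.

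More NKX3-1 peaks were called in HET than in WT prostates. The HET lists averaged 17744.5 ± 34.6 peaks (SD, n = 2) and the WT lists 12826.5 ± 2519 (SD, n = 2), a geometric mean ratio of 1.40. The peaks covered 12.2 ± 0.39 Mb (SD, n = 2) in HET and 8.15 ± 1.36 Mb (SD, n = 2) in WT, a difference of 0.59 on the log2 scale. Both HET lists exceeded both WT lists in number and covered length, and the exact permutation test gave p = 0.333 for each, the smallest value that 2 against 2 lists allow. The comparison depended on WT 2, without which the ratio of peak numbers was 1.21, and on WT 1, without which it was 1.61.

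Merging the 4 lists gave 23953 regions, of which 8298 (34.6%, 95% Wilson interval 34.0 to 35.2) were called in every WT and HET list. With only scores at or above 168.3, the median over all lists, 3979 regions were. The region with the highest mean score percentile lay on chromosome 2 at 6169214 to 6170215 (mouse build 37, as are all positions here), at percentile 99.98 or above in each list. It was the highest scoring peak of HET 2, with a score of 965.94. The next regions lay on chromosome 19 at 37211626 to 37212642, on chromosome 11 at 43820717 to 43821727, on chromosome 16 at 5670859 to 5671614 and on chromosome 11 at 49532495 to 49533702. Chromosome 2 held another 2 of the 10 leading regions, at 52612293 to 52613236 and at 137010550 to 137011684. Chromosome 18 also held 2, at 20885601 to 20886907 and at 44044839 to 44046454, and the last was on chromosome 8 at 97720486 to 97721323. These 10 regions were 756 to 1616 bp wide, and the median width of the regions shared by all lists was 795 bp. Their mean percentiles lay between 99.85 and 99.99.

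**Figure D1:**
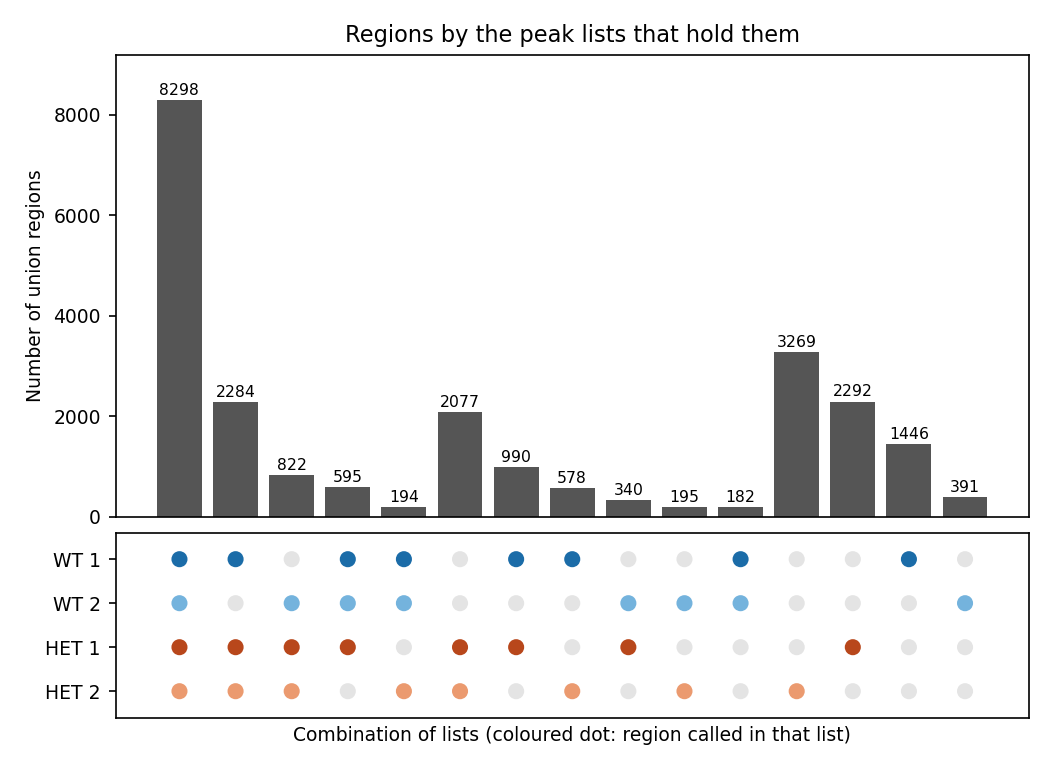
Number of union regions (y axis, linear from 0) for each combination of the 4 peak lists, shown by coloured dots under each bar. The 8298 regions of all 4 lists form the tallest bar, and 2077 regions were held by both HET lists alone against 182 by both WT lists alone.

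Nearly every region called in both WT lists was also called in HET prostate. Of 9269 such regions, 8298 were in both HET lists (89.5%, 95% Wilson interval 88.9 to 90.1) and 9087 in at least 1 (98.0%, 97.7 to 98.3). In the other direction, 8298 of 13481 regions of both HET lists were in both WT lists (61.6%, 60.7 to 62.4) and 11404 were in at least 1 (84.6%, 84.0 to 85.2). With the 11045 highest scoring peaks taken from every list, these shares for both lists of the other genotype were 77.3% and 76.4%. Equal lengths did not mean equal score limits. WT 2 was left uncut, with a lowest score of 100.01. The lowest score kept was 125.31 in WT 1, 147.3 in HET 1 and 145.05 in HET 2.

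WT-only regions numbered 182, or 1.96% of the regions of both WT lists (95% Wilson interval 1.70 to 2.27). There were 572 with equal list lengths (87 of them WT-only in the deposited lists), 81 with scores of 168.3 or more (2 of them) and 376 to 1628 when 1 list was left out. Another merging rule, another overlap rule and autosomes alone gave 176 to 202. Most of them had low scores, with a median percentile of 23.8 in WT 1 and 19.9 in WT 2. The leading one lay on chromosome 14 at 79462288 to 79463124, with scores of 225.28 in WT 1 and 177.47 in WT 2, at percentiles 69.9 and 56.6. It was followed by regions on chromosome 10 at 66390857 to 66391944, on chromosome 18 at 43995880 to 43996463 and on chromosome 13 at 120201119 to 120201798. The chromosome 18 region was the only WT-only region in the top 10% of a WT list, at percentile 93.2 in WT 1 and 24.7 in WT 2. The remaining 6 of the 10 had mean percentiles between 47.7 and 56.5 and lay on chromosomes 4, 5, 8 and 9.

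HET-only regions numbered 2077, or 15.4% of the regions of both HET lists (95% Wilson interval 14.8 to 16.0). There were 562 with equal list lengths (334 of them HET-only in the deposited lists), 1247 with scores of 168.3 or more (146 of them) and 2899 to 5346 when 1 list was left out. Their median percentile was 26.7 in HET 1 and 34.1 in HET 2. The leading HET-only region was on chromosome 6 at 31217862 to 31218833, with scores of 326.47 in HET 1 and 438.09 in HET 2, at percentiles 84.9 and 95.5. The next were on chromosome 5 at 32237010 to 32237825, on chromosome 13 at 97823304 to 97824489, on chromosome 10 at 116915794 to 116916556 and on chromosome 9 at 21989215 to 21989900. The other 5 of the 10 had mean percentiles of 79.0 to 81.1 and lay on chromosomes 2, 6, 14 and 19. A total of 8 HET-only regions were in the top 10% of HET 2 and 1 was in that of HET 1. The latter, named after its values were seen, lay on chromosome 13 at 120281367 to 120282771, at percentile 99.5 in HET 1 and 12.1 in HET 2.

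The excess of HET-only over WT-only regions was 11.4-fold with the deposited lists. It was 1.78-fold without WT 2, 6.88-fold without HET 1 and 15.4-fold with scores of 168.3 or more. That score limit left the HET lists longer, with 9195 peaks in HET 1 and 8889 in HET 2. WT 1 kept 7225 and WT 2 kept 5262. With lists of 11045 peaks each, the ratio was 0.983, a setting in which the other 2 splits of the lists also gave counts closer to each other. Splits of the 4 lists that ignore genotype also gave unequal counts. A total of 990 regions were called in WT 1 and HET 1 alone against 195 in WT 2 and HET 2 alone, and 578 in WT 1 and HET 2 alone against 340 in WT 2 and HET 1 alone. With scores of 168.3 or more, these counts were 628 against 91 and 250 against 158.

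Lists of the same genotype shared more sequence on average than lists of different genotypes, but not in every pair. The Jaccard index was 0.506 between the WT lists and 0.538 between the HET lists. Between genotypes it ranged from 0.437 for WT 2 and HET 2 to 0.518 for WT 1 and HET 1, above the value of the WT lists. The mean within genotypes exceeded the mean between them by 0.047, and the other 2 ways to pair the lists gave -0.019 and -0.028. Added together, these differences cancel by construction, so the negative values of the other 2 ways are no separate evidence. The difference for the genotype split was 0.018 with equal list lengths, 0.012 without HET 2 and 0.086 without WT 1. With only 3 such splits, the comparison cannot reach a share below 0.05. The order turned with the share of the shorter list as the measure, where the difference was -0.046.

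WT peaks were found in the HET lists more often than in the other WT list. HET 1 held 83.5% of the peaks of WT 1 (95% Wilson interval 82.9 to 84.1) and WT 2 held 63.6% of them (62.8 to 64.4). HET 1 held 91.2% of the peaks of WT 2 (90.7 to 91.7), and WT 1 held 84.0% (83.3 to 84.7). HET 2 held 77.9% of WT 1 peaks and 86.2% of WT 2 peaks. Longer lists overlap more peaks, and both HET lists were longer than both WT lists. Overlap was 79.8 to 115.4 times the mean of random shifts over the 12 ordered pairs, on average 93.7 times, and on average 248 times when a reciprocal overlap of 50% was required. No shift reached the observed overlap in any pair (permutation p = 0.001, the smallest that 1000 shifts allow). All lists were called against the same KO library, so part of this overlap may come from the shared control.

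Among the 8298 shared regions, the order of scores followed genotype less clearly. Spearman's rho across regions, which are not independent replicates, was 0.72 between the WT lists and 0.70 between the HET lists. It was 0.75 for WT 1 with HET 1 and 0.74 for WT 2 with HET 1. With HET 2 it was 0.58 for WT 1 and 0.62 for WT 2.

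The strongest peaks of each list were found almost everywhere, and the weakest mostly in some lists only. In the highest score decile, 99.2% of WT 1 peaks, 99.8% of WT 2 peaks, 99.3% of HET 1 peaks and 97.2% of HET 2 peaks overlapped a peak in all 3 other lists. In the lowest decile these shares were 16.7%, 38.9%, 4.9% and 10.4%. The gap between the highest and the lowest decile averaged 81.1 ± 14.4 percentage points (SD, n = 4 lists). Of the lowest decile of WT 1 peaks, 37.1% were in both HET lists (95% Wilson interval 34.7 to 39.6). Of the lowest decile of HET 1 peaks, 8.2% were in both WT lists (7.0 to 9.6). Both HET lists were longer than both WT lists, and these shares were not taken at equal list lengths. They do not show a difference between genotypes.

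**Figure D2:**
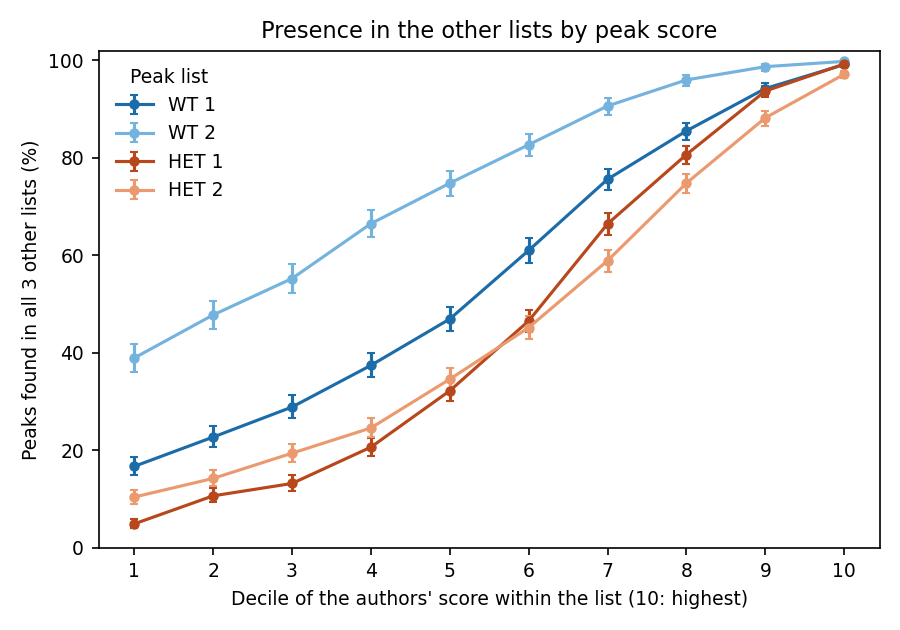
Share of peaks found in all 3 other lists (y axis, percent) by decile of the authors' score within each list (x axis), with 95% Wilson intervals as error bars. The share rises from 4.9 to 38.9% in the lowest decile to 97.2% or more in the highest.

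NKX3-1 peaks lay on all 19 autosomes and on chromosomes X and Y in each of the 4 lists. Chromosome 11 had the highest density in every list, from 5.26 peaks per Mb in WT 2 to 9.21 in HET 2. Chromosome 14 had the lowest density of the autosomes in every list, from 3.65 peaks per Mb in WT 2 to 5.93 in HET 2. Chromosome X held 1.57 to 2.61 peaks per Mb and lay below every autosome in every list. Its density was 0.359 ± 0.010 (SD, n = 4) of the autosomal density. Densities were not corrected for chromosome copy number, and the cause of the lower density on chromosome X was not tested. Of the regions shared by all lists, chromosome 11 held 492, or 4.04 per Mb, and chromosome X 183, or 1.10 per Mb.

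**Figure D3:**
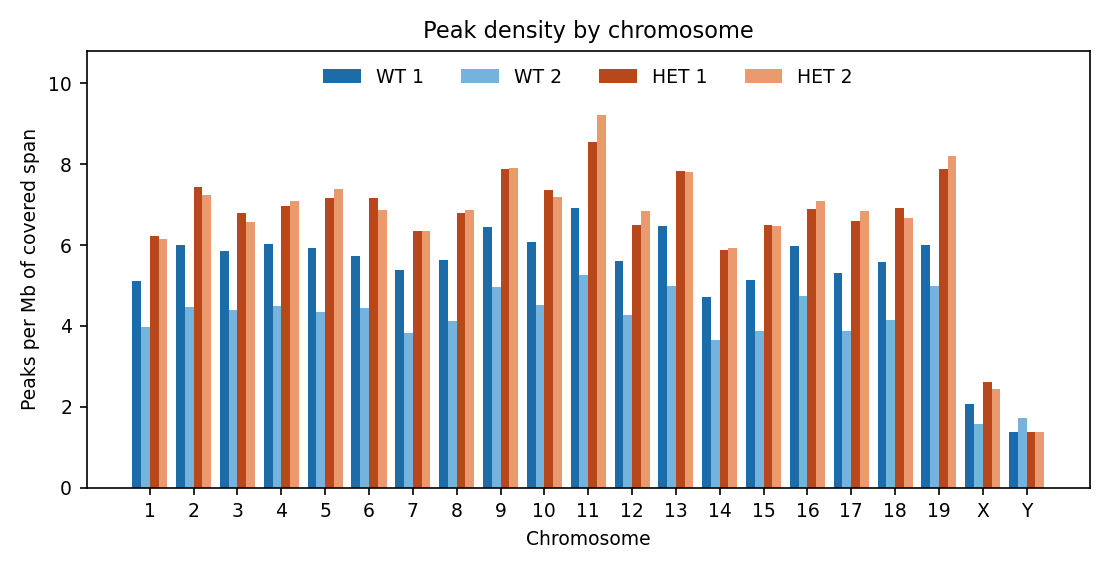
Peaks per Mb (y axis, linear from 0) on each chromosome (x axis) in the 4 peak lists, over the span from the chromosome start to the last called base. Chromosome X lies at 1.57 to 2.61 peaks per Mb, below the lowest autosome of each list.

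Summed over the 4 lists, the 1 Mb window with most peaks was on chromosome 6 at 134000001 to 135000000. It held 23 peaks in WT 1, 20 in WT 2, 32 in HET 1 and 35 in HET 2. These fell into 43 regions, of which 13 were in all 4 lists and 7 were HET-only. The window on chromosome 4 at 59000001 to 60000000 held 39 regions, 17 of them in all lists. The window on chromosome 2 at 70000001 to 71000000 held 29 regions, 17 of them in all lists and none HET-only or WT-only. Its peaks numbered 28 in WT 1, 19 in WT 2, 26 in HET 1 and 25 in HET 2. The sum gives the longer HET lists more weight. In WT 1 the chromosome 6 window held fewer peaks than the chromosome 2 window. In WT 2 it held fewer than the chromosome 4 window, which had 21. The mean over 2650 windows was 9.04 regions.

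**Figure D4:**
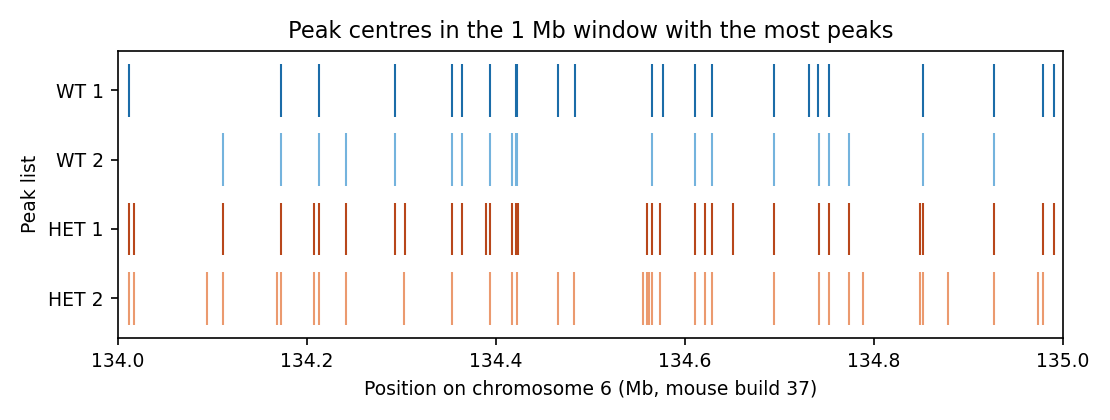
Centres of peaks (vertical lines) in the 4 lists (y axis) along chromosome 6 from 134000001 to 135000000 (x axis in Mb, mouse build 37). The window was chosen by the sum of peaks over the 4 lists. It holds 23 and 20 peaks in the WT lists and 32 and 35 in the HET lists.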

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

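The test in this part was chosen after the result was seen. The list filed for the KO library held 2 rows although that library was the control of the peak caller, and it was used in no comparison. The rows lay on chromosome Y at 2898358 to 2901273 and at 2901392 to 2902259, with scores of 1728.34 and 637.05 and peak numbers 14607 and 14608. A candidate explanation is rows copied from the WT 1 list. All 2 rows equalled a WT 1 row in position, number and score, and neither equalled a row of WT 2, HET 1 or HET 2. Peak numbers of this size in a list of 2 rows also argue against separate calling in KO. No biological explanation was tested, and the list gives no information on antibody signal in KO prostate.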

How the results depend on the processing

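The leave-one-out values for overlap, score deciles and chromosome X, the block value of pairs between genotypes, the other values for chromosome X, and all alternatives for the ratio of HET-only to WT-only regions and for the shares found in the other genotype were chosen after seeing the data. Across 12 results, 61 of 84 alternative values kept their direction or, by kind, stayed within 1.5 times the reported value (counts and their ratio), its 95% interval (shares) or 1 SD (score deciles, chromosome X). Of the others, 20 moved and 3 changed sign or side. Not all of the 61 could have come out otherwise. For peak number and covered length, the replicate block equals the reported value by construction. Both HET lists exceeded both WT lists, so leaving out 1 list could not turn these differences. The leave-one-out values of overlap against chance were counted as kept without a limit. The tally is therefore no measure of robustness. With equal list lengths, 572 regions were WT-only and 562 HET-only, a ratio of 0.983 against 11.4, and 77.3% and 76.4% of the regions of both WT and both HET lists were found in the other genotype. Of those 572 and 562, 87 and 334 lay in the same class with the deposited lists. With only scores at or above the median of 168.3, the counts were 81 WT-only, 1247 HET-only and 3979 in all lists, and these shares were 88.4% and 59.0%. Of those 81 and 1247, 2 and 146 lay in the same class with the deposited lists. Leaving out each replicate in turn, WT-only regions numbered 376 to 1628, HET-only regions 2899 to 5346, and their ratio was 1.78 (without WT 2) to 11.6. The difference in Jaccard index within and between genotypes became -0.046 with the share of the shorter list. Chromosome X density relative to autosomes was 0.311 with the higher scores and 0.343 with equal list lengths. The cause of these changes was not tested, except that stricter lists hold fewer peaks and a missing list loosens the class by construction. With the replicate block, the log2 ratio of HET to WT peak number was 0.48 as without it (sign-flip permutation p = 0.5, the smallest that 2 pairs allow), and covered length kept 0.59. Pairs with the same number differed from other pairs by -0.019 in Jaccard index, but the other pairs include both within-genotype pairs. Among pairs between genotypes the difference was 0.0065. Rank deviations of same-numbered lists correlated at 0.07 over 8298 regions. The numbers are not treated as pairs. The lists give no depth, so a region missing from a list cannot be told from one below the caller's limit.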

Other observations

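The tests of chromosome segments, gene dose, chromosome Y and regions at percentile 50 or more below were chosen only after the result was seen, and the list-length, median score and spacing tests before. NKX3-1 regions lay close together. Of all 23953 regions, 39.6% had another region within 10 kb, against 18.2% on average and 19.2% at most in 1000 random placements on the same chromosomes (permutation p = 0.001, the smallest they can give). Among the 8298 regions of all lists, 19.7% had another such region within 10 kb, against 6.84% by random placement. HET-only regions lay within 5 kb of a region of all lists in 8.62% of cases, against 3.58% by random placement (permutation p = 0.001). WT-only regions did so in 9.89% and regions of a single list in 6.68 to 8.35%, so the closeness is not shown to be particular to HET-only regions. Random placement ignores gene content and unmappable sequence, which could also bring regions together.

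Of 2657 regions in the top 10% of at least 1 list, 2587 (97.4%) were called in all 4. The 70 others were missing mostly from WT 2 alone (42 regions). A further 9 were missing from WT 1 alone, 7 from HET 2 alone, 2 from HET 1 alone, 9 from both WT lists and 1 from both HET lists. The following regions were picked after their values were seen. A region on chromosome 7 at 17510539 to 17511372 was at percentile 93.2 in WT 1, 94.1 in HET 1 and 98.2 in HET 2 and was not called in WT 2. A region on chromosome 13 at 120281367 to 120282771 was at percentile 99.5 in HET 1 and 12.1 in HET 2 and in no WT list. It was the last region called on that chromosome in any list.

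HET-only regions outnumbered WT-only regions by 2077 to 182. Chromosome segments that differ between the mice in strain origin or copy number are argued against as the whole cause, since 254 of 259 windows of 10 Mb with 20 or more other regions (98.1%) held more HET-only than WT-only regions. HET-only regions were still somewhat clustered, with 8.71% of them in 1 Mb windows that held 5 or more, against 5.99% on average when the label was permuted among regions (permutation p = 0.011). The largest number in a window was 9, and permutations reached 12 (permutation p = 0.0949). A contribution of local segments stays open. At percentile 50 or more in both lists of their genotype were 130 HET-only and 2 WT-only regions, a ratio of 65. This cannot decide on weak sites close to the caller's limit. A percentile in the HET lists does not show how far a site lies from the limit in the WT lists. Of HET 1 peaks in score decile 6, 51.1% were in both WT lists. Weak sites stay open for these 130 and for the other 1947 HET-only regions. The median percentiles of HET-only regions, 26.7 and 34.1, do not decide it, because those of WT-only regions were low as well (23.8 and 19.9). The part of the longer HET lists stays open too. The ratio was 0.983 with equal lengths, but these changed the other splits as well. For WT 1 and HET 1 against WT 2 and HET 2, the larger over the smaller count went from 5.08 to 1.19. The remaining split went from 1.70 to 1.39 with its larger side reversed. WT 1 and HET 2 alone held 578 regions against 340 in WT 2 and HET 1 before, and 342 against 476 after. What made the HET lists longer stays open: sequencing depth, antibody yield and Nkx3-1 gene dose cannot be told apart here, because depth is unknown and the exact permutation p of 0.333 is the smallest the design allows.

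The highest scoring peak of WT 1, WT 2 and HET 1 lay on chromosome Y at 2898358 to 2901314, next to a second region at 2901384 to 2902420, and neither was called in HET 2. Chromosome Y missing from the HET 2 library is argued against, since HET 2 had 4 other chromosome Y regions, against 2 in WT 1, 3 in WT 2 and 2 in HET 1. The wider region was the widest peak of both WT lists and ranked 4 by width in HET 1. The second region was the last one called on the chromosome in any list. This does not place it at an assembly edge, because chromosome lengths were not used. A repeat or assembly edge that piles up reads could give so wide a peak, though the sequence was not examined. Width cannot separate this from binding, because the same peak also had the highest score. Peaks were called against the KO library, whose signal there is unknown. Both a difference between mice in such a repeat and a difference in NKX3-1 binding stay open, the latter untested.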
